A study of Rattus norvegicus with 3 samples.

How the data were processed

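RNA of rat induced pluripotent stem (iPS) cells of the line M13 was compared with 1 RNA mix, mix1, of cultured rat bone marrow cells and primary ear fibroblasts on 3 two-colour whole-genome rat arrays. Each array carried an iPS M13 sample in Cy3 and mix1 in Cy5, per the labels, so all ratios ran the same way and no dye was swapped. All 3 arrays lay on 1 slide and were scanned on 1 date, per the file headers. The labels put all 3 samples in 1 group.

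Spot intensities were deposited as the scanner software gave them, with mean and median pixel brightness and local background per channel and no background subtracted. Agilent Feature Extraction is named in the submitters' processing notes, and its version, 9.5.3.1, in the file headers. Processed intensities in the same files were background-detrended and dye-normalized by that software, per the file headers. The log10 ratios in those files were Cy5 over Cy3 of the processed signals, per the file headers. The authors' value table held log2 ratios whose direction and scale were not stated. Set against the log10 ratios of each array, its columns had slopes of -3.32 and correlations of -0.99987, -0.99996 and -0.99986 for replicates 1, 2 and 3 across probes, so it was taken as log2 of Cy3 over Cy5. Column medians were -0.0413, -0.0282 and -0.0286, and whether the authors centred the columns stays unknown. Every column was mapped to a sample. Probe positions refer to build rn3, per the file headers.

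Probe names came from the array design and were updated through a table of RefSeq genes. Of 41012 probes, 10735 matched by RefSeq accession, 5577 by symbol, 3730 by synonym, 1217 by gene ID and 35 by a further accession, and 19718 kept the name in the file. This changed the symbol of 8698 probes, and 21242 probes had a symbol that was not a placeholder. No genome sequence was used here.

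Mean spot signals and median local backgrounds were corrected by normexp with an offset of 50 and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Nothing was done between arrays. Spots marked as non-uniform or population outliers in either channel were left out, namely 205, 263 and 192 on replicates 1, 2 and 3. Saturated spots were kept, of which there was 1, in the iPS M13 channel of replicate 1. Spots of a probe were averaged. A probe was kept if it was well above background in the same channel on all 3 arrays, which 24177 probes were and 16835 were not. The brightest kept probe stood for each gene, giving 20343 genes, 10828 with a symbol. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled names and figures.

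Median spot signals were 272, 291 and 289 in Cy3 and 228, 254 and 235 in Cy5 on replicates 1, 2 and 3, against negative control medians of 76.0, 77.4 and 77.1 in Cy3 and 60.9, 61.2 and 63.7 in Cy5. The median SD of a log2 ratio between arrays was 0.0339. The arrays were compared on 178 probes with 10 spots each. The mean of 10 spots had a median SD between arrays of 0.0195, against 0.0139 from spot noise alone, and 36.5% of these probes differed between arrays by a test over spots. Robust SDs of the difference between pairs of arrays were 0.0595, 0.0527 and 0.0615, against 0.0623 from spot noise of single spots. These values cannot show whether the arrays held separate samples, since repeat hybridisations would also differ by more than spot noise. Each array was counted as 1 replicate because the labels give each as a sample.

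The mean log2 ratio of iPS M13 over mix1 was tested against 0 with lmFit and eBayes, with 1.55 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1, chosen because small dye effects cannot be separated from the group. mix1 entered as 1 control RNA, so its own spread is left out. With 3 arrays an exact two-sided sign-flip test cannot give a p below 0.25, so no such test was used for calls. Where 1 RNA was not well above background on any array for any probe of a gene, the bound divided the bright RNA's mean by the dim RNA's, taken per array as the higher of the probe's own signal and the lowest signal well above background, after loess and Aquantile scaling. That lowest signal was at a log2 of 7.35, 4.72 and 7.14 for mix1 on replicates 1, 2 and 3. On replicate 2 it could thus leave a dim signal unchanged, and for Pou5f1 and Lama1 the bound equalled the measured ratio. Bounds hold for the probe used and the main settings. Those under 1 are not given.

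The 39 gene lists, the comparison, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest called genes with a symbol, measured in both RNAs on all arrays with 1 sign. It added 19 genes whatever their result, namely Pou5f1, Sox2, Klf4, Myc, Nanog, Zfp42, Lin28a, Tdgf1, Dnmt3b, Dnmt3l, Cdh1, Epcam, Alpl, Fut4, Cdh2, Thy1, Vim, Col1a1 and Ptprc. It further added, from each list, up to 4 called members with the largest ratios and up to 2 against the list's median, and the 5 largest bounds in each direction. Some genes that the rule takes are not reported here. The lists covered pluripotency, epithelial junctions, cell division, DNA replication, DNA repair, chromatin, germline, endoderm, mesoderm, neuroectoderm, trophoblast, fibroblasts, TGF-beta and injury response, matrix enzymes, hematopoietic cells, macrophages, neutrophils, lymphocytes, erythroid cells, marrow stroma, endothelium, muscle, keratinocytes with cartilage and melanocytes, Hox genes, imprinted genes, MHC class I, interferon response, inflammatory cytokines, senescence and p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosomes, ribosomal proteins, ribosome biogenesis and MYC targets, LIF and STAT3 signalling, WNT and BMP signalling, sex-linked markers and housekeeping genes. Lists with at least 5 measured genes were tested by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives.

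Other alternatives changed the background correction, the spot statistic, the normalization within and between arrays, the filter on dim probes, outlier spots, the probes of a gene, the variance model and the threshold, used the processed signals or the value table, or left out each replicate. Correction of the ratios for probe GC content was added after the data were examined. Slide or scan date as a block was not run, since all arrays shared both.

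The steps were tested on simulated data for iPS M13 against mix1 over 20343 genes, with 50 genes changed at each fold. All 50 were called at 3-fold, 8-fold and 64-fold, with median estimates of 2.88-fold, 7.43-fold and 55.2-fold. At 1.5-fold, under the minimum fold, 0 were called, and 0 unchanged genes were called. These changed genes were few, bright in both channels and split evenly between higher and lower. In the real data 845 genes were called at least 16-fold lower and 76 at least 16-fold higher. The simulation therefore does not show how loess handles that imbalance or how dim genes behave. A list shifted by 1 on the log2 scale was called, at 0.985. Camera with its preset correlation also called 4 of the other lists, with medians of up to 0.190 in size. The shifted lysosome list shared Ctsb with the matrix enzymes and Gusb with the housekeeping genes, so some of these calls may reflect shifted members. A call of a list with a small median is thus weak evidence of a shift of the list. A simulated GC slope of -0.30 was estimated at -0.28 within genes and -0.27 across genes.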

Results

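Gene expression was measured in rat induced pluripotent stem (iPS) cells of the line M13, which are adult cells reprogrammed to an embryonic stem cell-like state, and in adult rat cells. The 3 iPS M13 samples, grown on irradiated mouse embryonic fibroblast feeders, were each labelled with Cy3 and hybridised against the same adult RNA labelled with Cy5. That RNA, named mix1, combined cultured bone marrow cells with primary fibroblasts of the ear. Each of the 3 two-colour whole-genome rat arrays held 45018 spots, of which 43379 carried probes for 41012 different rat sequences. In the iPS M13 channel 58.5%, 60.8% and 53.5% of the probes were well above background on replicates 1, 2 and 3, and in the mix1 channel 57.7%, 61.0% and 52.4%. Log2 ratios of iPS M13 over mix1 correlated at 0.997 to 0.998 between arrays across genes, which are not independent replicates. The number of arrays limits the precision of every value. The labels do not say that the 3 samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

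The comparison asked how the transcript levels of iPS M13 cells differ from those of the adult cell types in mix1. Of the measured genes, 36 of 37 fibroblast, 20 of 20 macrophage and 14 of 15 inflammatory genes were lower in iPS M13 than in mix1 (adjusted p = 0.336 with an estimated correlation for each list). The collagen Col3a1 had a log2 ratio of -10.79 ± 0.16 (SD, n = 3). Higher were 11 of 18 epithelial junction, 16 of 27 cell division, 15 of 20 DNA repair and 19 of 26 ribosome biogenesis genes, and 0 of them were lower (adjusted p = 0.309 to 0.363 with an estimated correlation). With 3 arrays that list test has few degrees of freedom, so its p-values decide little. The de novo DNA methyltransferase Dnmt3b (4.10 ± 0.08) and the transcription factor Sox2 (2.62 ± 0.07) were higher too. Of 20343 genes tested, 3808 (18.7%) were called higher in iPS M13 and 5184 (25.5%) lower. Large differences lay mostly on the lower side: 845 genes were at least 16-fold lower and 76 at least 16-fold higher. Of the 8992 called genes, 8981 had the same sign on all 3 arrays.

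Genes were called by limma at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold difference. Since 19544 of the 20343 genes passed the adjusted p alone, the minimum fold decided nearly all calls. The test set the mean ratio against 0, so it leaves out the spread of mix1, which was 1 control RNA, and without a dye swap, dye and group cannot be told apart. The balance of calls depended on the scaling of the arrays. Loess gave 42.3% of the calls as higher and median centring 67.2% (7400 higher, 3616 lower). No within-array normalization gave 65.1% (7005 higher, 3753 lower), and the scanner software's processed signals, like the authors' value table, gave 56.6% (6319 higher, 4842 lower). The median log2 ratio of all genes, -0.03 after loess, moved up by 0.60, 0.55 and 0.32 in these settings. Ratios of that size have a sign only relative to the scaling. Across genes, which are not independent replicates, log2 ratios also fell by 0.43 per 10% of probe GC content.

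**Figure D1:**
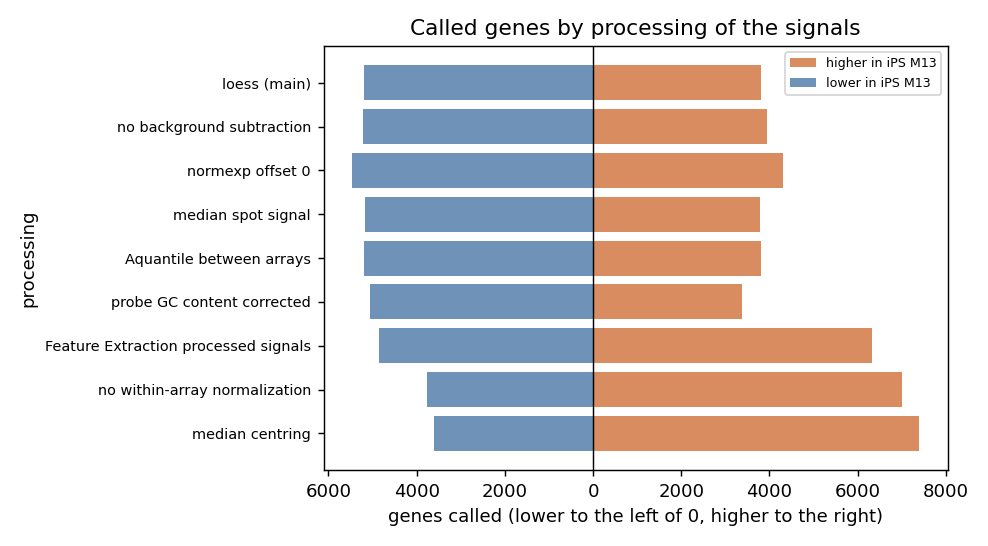
Bars count genes called lower (blue, left of 0) and higher (orange, right of 0) in iPS M13 under 9 ways of processing the signals, named on the vertical axis. Higher calls run from 3378 after correction for probe GC content to 7400 under median centring, and lower calls from 3616 under median centring to 5466 with a background offset of 0.

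Among the genes fixed in advance, the reprogramming factors did not move together. Sox2 was higher in iPS M13, with its probe on chromosome 2 from 120914687 to 120914746 in build rn3. Pou5f1 (Oct4), the central pluripotency factor, was at least 2.48-fold higher, since mix1 was not well above background there on any array (adjusted p = 9.00e-05, higher on 3 of 3 arrays). Klf4, whose probe lies on chromosome 5 from 73452107 to 73452166, had a log2 ratio of -6.89 ± 0.05, and the growth regulator Myc one of -5.71 ± 0.03, both lower on all 3 arrays (adjusted p = 6.54e-07 for each). The adhesion molecules Epcam (4.71 ± 0.13, with mix1 measured on 2 of 3 arrays) and Cdh1 (3.07 ± 0.07) were higher, as was Cdh2 (1.17 ± 0.01), which no longer reached 2-fold once the trend of the ratios with probe GC content was taken off (0.78). Alkaline phosphatase Alpl was lower, at -2.52 ± 0.05. Lin28a (-0.16 ± 0.04) and Fut4 (-0.41 ± 0.04) were not called, and their sign turned under other settings, up to 0.40 for Lin28a after GC correction and 0.41 for Fut4 under median centring. The fibroblast and mesenchymal markers Vim (-5.26 ± 0.08) and Col1a1 (-7.09 ± 0.19) were lower, Thy1 was at least 24.6-fold lower, and the blood cell antigen gene Ptprc was at least 1.83-fold lower. Nanog, Zfp42 and Tdgf1 had no probe under their names, and Dnmt3l was not well above background in either RNA on all arrays.

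**Figure D2:**
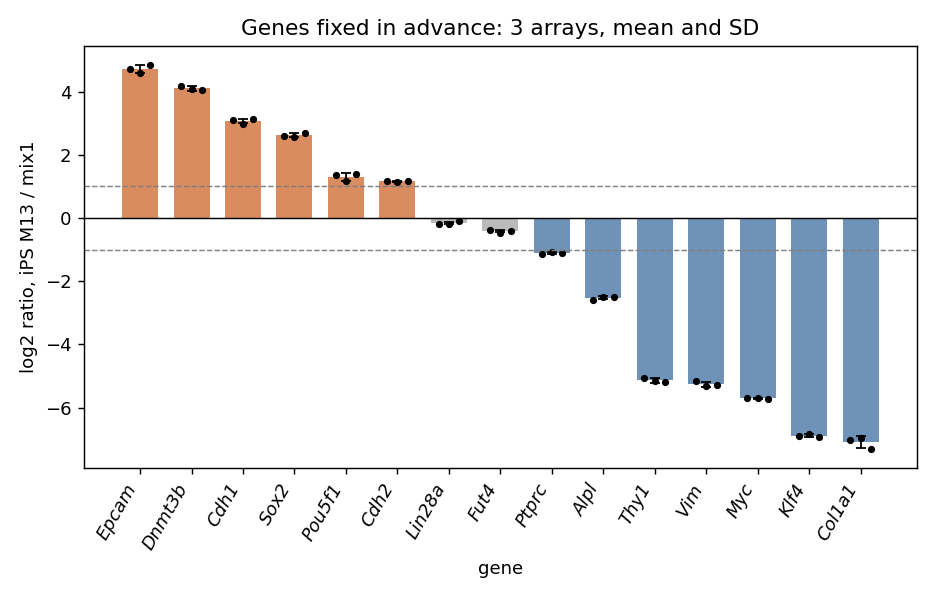
The vertical axis gives the log2 ratio of iPS M13 over mix1 for each gene fixed in advance that was measured; bars are means of 3 arrays, whiskers SDs, dots arrays, and dashed lines mark 2-fold. Orange bars were called higher, blue bars lower and grey bars not called; values run from 4.71 for Epcam to -7.09 for Col1a1, and Pou5f1, Ptprc and Thy1 are measured values where 1 RNA was not well above background.

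The 39 gene lists were fixed before the data were examined, and 34 of them had at least 5 measured genes and were tested. Camera with its preset correlation called 8 lists higher in iPS M13 and 17 lower. With an estimated correlation camera called 0 lists, at adjusted p-values from 0.309 to 0.612. With 3 arrays that estimate leaves few degrees of freedom, so hardly any list could be called and these p-values decide little. Fry, which tests whether the genes of a list move 1 way without comparing them with other genes, called all 34. Counts adjusted over the list alone equalled those over all genes tested in every list. A gene not well above background in 1 RNA on any array is given only as at least N-fold, from the level of the brighter RNA over that of the dimmer one, taken at no less than the floor. With such genes at their bounds, list medians were 1.06 for neuroectoderm, -6.28 for fibroblast, -4.89 for TGF-beta and injury response, -4.73 for matrix enzymes, -1.95 for hematopoietic, -5.11 for macrophage, -2.05 for marrow stromal, -1.48 for muscle, -2.52 for keratinocyte, -1.23 for cholesterol synthesis and -2.35 for WNT and BMP genes.

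Several list medians moved by more than 1.5 times with the processing. Without the filter on dim probes they were 0.56 for pluripotency, 0.48 for epithelial, 0.65 for neuroectoderm, -1.21 for marrow stromal and -0.18 for keratinocyte genes. Among lists not called they were -0.29 for mesoderm, -0.04 for trophoblast, 0.09 for erythroid, -0.20 for endothelial, 0.29 for Hox and -0.22 for imprinted genes. With both channels above background, keratinocyte genes were at -0.56, MHC class I genes at -1.46 and imprinted genes at -0.26. With the processed signals, medians were 2.04 for pluripotency, 2.80 for epithelial, 2.39 for neuroectoderm, 1.54 for erythroid, 1.63 for Hox, -3.26 for hematopoietic, -3.22 for marrow stromal and -2.80 for muscle genes. Under median centring, they were 1.99 for cell division, 1.79 for replication, 2.23 for repair, 1.52 for chromatin and 1.84 for ribosome biogenesis genes. In that setting they were -1.68 for MHC class I, -1.20 for senescence, -1.39 for LIF and STAT3, -0.72 for cholesterol, -0.08 for glycolysis and 0.98 for oxidative phosphorylation genes. Of named genes measured in both RNAs on at least 1 array, Lef1 (4.29), Oasl (2.89), Myh3 (2.07) and Plac1 (-1.67) were larger in size with the processed signals. Cdh2 (1.99), Ascl2 (2.19), Nes (1.90), Il18 (2.21) and Ctsz (1.95) were higher and Gusb (-1.15) was less low under median centring. Averaged over their probes, Nppb was at 3.09 and Dio3 at -2.71, and Nes no longer reached 2-fold (0.98).

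Among proliferation and growth genes, each list had members called higher and 0 called lower. Of 27 measured cell division genes, 16 were higher and 0 lower, led by cyclin Ccna2 (log2 ratio 2.22 ± 0.03) and the spindle checkpoint kinases Bub1b (2.08 ± 0.04) and Bub1 (2.02 ± 0.01). The list had a median of 1.15 and a camera adjusted p = 1.40e-05 (adjusted p = 0.309 with an estimated correlation). DNA replication genes had 15 of 31 higher and 0 lower, among them the primase subunit Prim1 (2.10 ± 0.01) and the origin recognition gene Orc1 (2.03 ± 0.02). Their median was 0.97, at an adjusted p = 1.40e-06 (adjusted p = 0.309 with an estimated correlation). DNA repair genes had 15 of 20 higher and 0 lower, with the nuclease Exo1 at 3.07 ± 0.01 and the checkpoint kinase Chek1 at 2.72 ± 0.02 and a median of 1.45 (adjusted p = 1.40e-05, and adjusted p = 0.309 with an estimated correlation). Ribosome biogenesis and MYC target genes had 19 of 26 higher and 0 lower, with Mybbp1a at 1.91 ± 0.04, Gnl3 at 1.72 ± 0.08 and a median of 1.21 (adjusted p = 1.40e-05, and adjusted p = 0.336 with an estimated correlation), while Myc itself was lower. Chromatin and DNA methylation regulators had 7 of 22 higher and 0 lower, led by Dnmt3b and the Polycomb methyltransferase Ezh2 (1.73 ± 0.01). Their median was 0.70 (adjusted p = 1.40e-05, and adjusted p = 0.309 with an estimated correlation).

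Among pluripotency and epithelial genes, more were called higher than lower. In the pluripotency network 9 of 18 measured genes were higher and 3 lower, with a median of 0.92. Many members of the list, among them Esrrb, Sall4 and Nodal, were not measured. A gene dim in mix1 counted as measured only where iPS M13 was well above background, so genes dim in both RNAs dropped out. The threonine dehydrogenase gene Tdh (3.13 ± 0.01) and Sox2 were among the higher genes, and Klf4 and Klf2 (-5.21 ± 0.08, iPS M13 measured on 1 of 3 arrays) among the lower ones. The list was called at an adjusted p = 0.0494 (adjusted p = 0.440 with an estimated correlation), and its call ended under 8 other settings, among them median centring, the processed signals and the filter on both channels. Epithelial junction genes had 11 of 18 higher and 0 lower, with the keratin Krt18 at 3.42 ± 0.04, the tight junction gene Ocln at 3.40 ± 0.17 (mix1 measured on 1 of 3 arrays), Epcam and Cdh1. Their median was 1.59, or 1.28 with unmeasured sides at their bounds. Their adjusted p was 0.0315 (adjusted p = 0.363 with an estimated correlation). The call ended when both channels had to be above background (median 1.03).

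Lineage genes went in different directions. Neuroectoderm genes had 6 of 9 higher, including the neurogenic factor Neurog1 (mix1 measured on 1 of 3 arrays), and 0 lower. The eye and brain regulator Pax6 was at least 12.5-fold higher and Map2 at least 2.03-fold higher. Of the 6, only Nes (1.06 ± 0.02) had mix1 well above background on all 3 arrays. Averaged over its probes, Nes no longer reached 2-fold (0.98). The list median was 1.13 (adjusted p = 0.00798, and adjusted p = 0.336 with an estimated correlation). Sox3 was called higher from its brightest probe, with mix1 not well above background, and another of its probes was called lower. Of 15 measured genes on a list of neuron genes made after the data were examined, 11 were higher and 2 lower, with Stmn2 at 2.58 ± 0.03. Early mesoderm genes had 1 of 8 higher, Isl1 (3.01 ± 0.14), and 4 lower, and the list was not called (adjusted p = 0.212). The lower ones included Snai1 (-6.58 ± 0.14, and -3.97 from another probe) and Pdgfra (-4.77 ± 0.02). The early endoderm list had 4 measured genes and was not tested: the yolk sac protein gene Afp was higher (3.82 ± 0.18, mix1 measured on 2 of 3 arrays), Lama1 was at least 3.43-fold higher, Dab2 was at -6.51 ± 0.02 and Gata6 was at least 5.29-fold lower. Trophoblast genes had 1 of 6 higher, Ascl2 (1.38 ± 0.25), and 3 lower, at an adjusted p = 0.213. Their Plac1 (-1.01 ± 0.58, iPS M13 measured on 1 of 3 arrays) lost its call without replicate 1 (-1.15) or without replicate 3 (-0.68), and under 4 other settings. Of 4 measured germline genes, Piwil2 (3.89 ± 0.14) and Kit were higher and Tfap2c was at least 2.92-fold lower.

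Hox and imprinted genes split. Of 15 measured Hox genes 7 were higher, among them Hoxd13 (4.07 ± 0.16, mix1 measured on 1 of 3 arrays) and Hoxa9 (3.41 ± 0.03), and 6 lower, among them Hoxa2 (-3.60 ± 0.04) and Hoxc10, which was at least 15.9-fold lower. The median of 0.99 and the mean of 0.00393 differed, and the list was not called (adjusted p = 0.342). Imprinted genes had 4 of 14 higher, with Snrpn at 2.36 ± 0.04 and the growth inhibitor Cdkn1c at 1.84 ± 0.05, and 7 lower, with Dio3 at -4.42 ± 0.05 and Igf2r at -4.06 ± 0.03 (adjusted p = 0.338 for the list). The only measured sex-linked marker, Uty, named after its value was seen, was not called from its brightest probe (0.55 ± 0.01), while another of its probes was called higher (1.38).

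Fibroblast and matrix genes were nearly all lower in iPS M13. Of 37 measured fibroblast genes 36 were lower and 1, Cdh2, higher, with a median log2 ratio of -6.29. The proteoglycan Dcn was at -10.37 ± 0.10, S100a4 at -8.90 ± 0.21 (-9.78 and -6.56 from its other probes), and the matricellular protein gene Postn at least 259-fold lower. Camera gave an adjusted p = 6.16e-08 for the list (adjusted p = 0.336 with an estimated correlation). Col1a1 and Vim were still well above background in iPS M13 on all 3 arrays, at mean log2 signals of 11.41 and 12.87 against 18.51 and 18.13 in mix1. The feeders were mouse fibroblasts, and hybridisation of their RNA to these probes was not tested. Matrix remodelling enzymes had 18 of 19 lower and 0 higher, with the inhibitor Timp2 at -8.95 ± 0.13 and the gelatinase Mmp2 at -8.14 ± 0.10 (-5.89 from another probe). The list had a median of -4.84 (adjusted p = 1.40e-05, and adjusted p = 0.309 with an estimated correlation). TGF-beta and injury response genes had 17 of 18 lower and 0 higher, with Myl9 at -9.03 ± 0.05 (-6.01 from another probe) and Ccn2 at -8.48 ± 0.06. The list had a median of -4.99 (adjusted p = 1.40e-05, and adjusted p = 0.336 with an estimated correlation). Smooth and skeletal muscle genes had 9 of 10 lower, with Tagln at -6.15 ± 0.05, and Myh3 was higher at 1.06 ± 0.17 (mix1 measured on 1 of 3 arrays), a call that ended without replicate 1 (0.96). Their median was -1.50, at an adjusted p = 0.0191 (adjusted p = 0.363 with an estimated correlation).

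All 20 measured macrophage and myeloid genes were lower, with the lipopolysaccharide co-receptor Cd14 at -7.49 ± 0.05, the lysozyme gene Lyz2 at -7.43 ± 0.06 and the protease gene Ctss at least 92.0-fold lower from its brightest probe (log2 ratio -6.01 from another). Their median was -5.49 (adjusted p = 1.40e-05, and adjusted p = 0.336 with an estimated correlation). Hematopoietic genes had 13 of 16 lower, with the leukocyte integrin Itgb2 at -5.99 ± 0.09 and Laptm5 at -5.42 ± 0.02, and 1 higher, Kit, given without a fold because mix1 was not well above background for the probe used on any array, while another Kit probe was above it on 1 of 3 arrays. Their median was -2.11, at an adjusted p = 0.00107 (adjusted p = 0.363 with an estimated correlation). Without the filter on dim probes another Kit probe was used and the gene was not called (0.18). Marrow stromal, bone and fat genes had 11 of 14 lower, with the chemokine Cxcl12 at -7.49 ± 0.08 and Spp1 at -5.12 ± 0.03. Higher were 2, the adipokine gene Adipoq (3.81 ± 0.13, mix1 measured on 2 of 3 arrays) and Nes (1.06 ± 0.02, under 2-fold at 0.98 averaged over its probes). The list median was -2.10, at an adjusted p = 0.0275 (adjusted p = 0.363 with an estimated correlation). Of 3 measured neutrophil genes 2 were lower, Lcn2 (-5.91 ± 0.06, iPS M13 measured on 2 of 3 arrays) and Camp (at least 1.66-fold), and of 3 lymphocyte genes 1, Ebf1 (-6.75 ± 0.10, iPS M13 measured on 2 of 3 arrays). Erythroid genes had 2 of 5 higher, the transferrin receptor Tfrc (1.89 ± 0.02) and Sptb (at least 1.84-fold), and 1 lower, at an adjusted p = 0.193. Endothelial genes had 3 of 6 lower, including Egfl7 (-3.19 ± 0.05) and Eng, at least 12.5-fold lower, and Tek at least 3.45-fold higher (adjusted p = 0.133). Keratinocyte, cartilage and melanocyte genes had 6 of 9 lower and 0 higher, with Comp at -5.74 ± 0.05 and Sox9 at least 35.7-fold lower from its brightest probe (log2 ratio -3.52 from another). Their median was -2.70, at an adjusted p = 0.0315 (adjusted p = 0.336 with an estimated correlation). That call ended when both channels had to be above background and after correction for probe GC content.

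**Figure D3:**
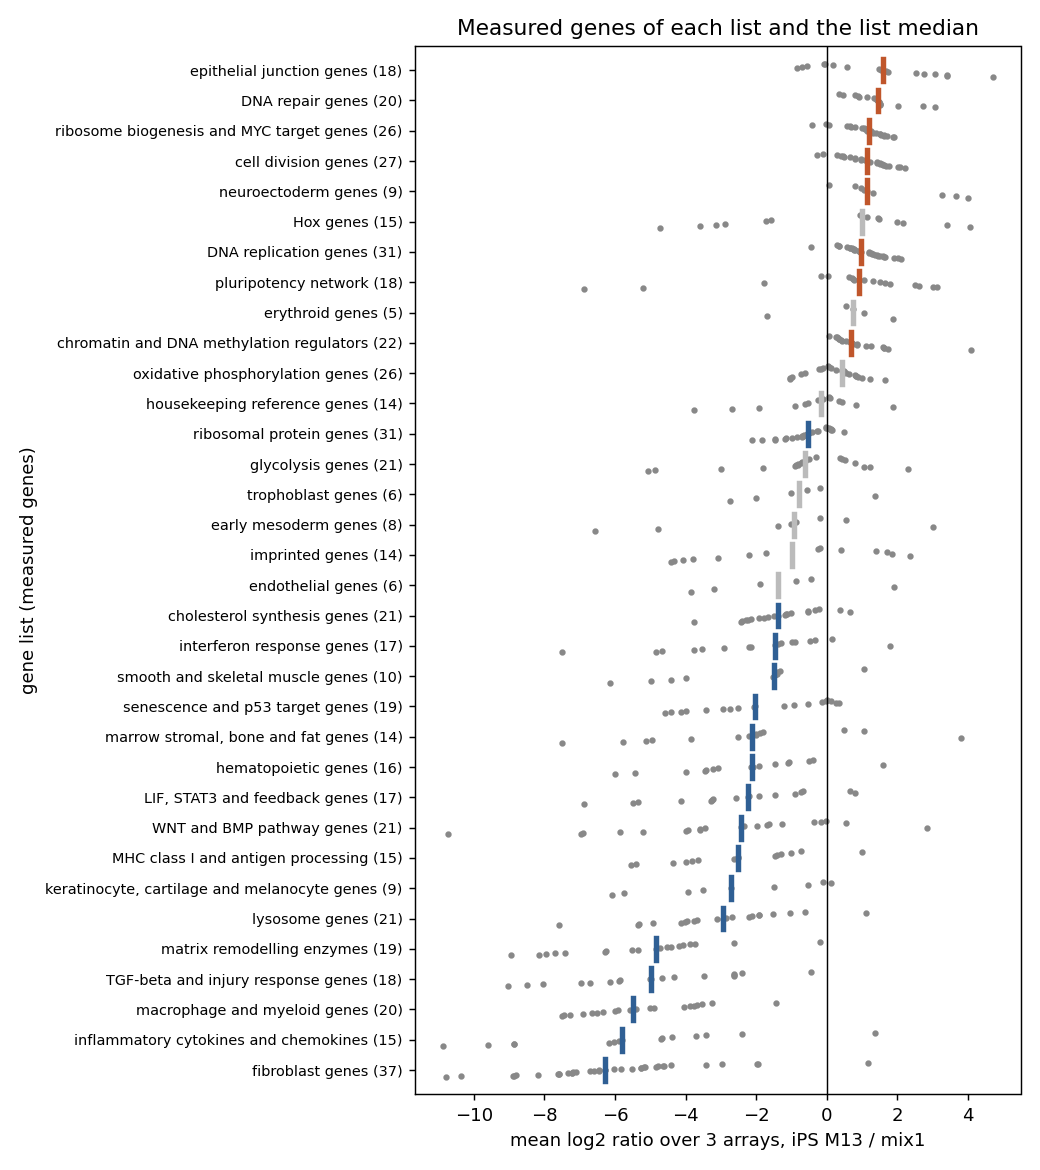
The horizontal axis gives mean log2 ratios of iPS M13 over mix1 over 3 arrays; grey dots are the measured genes of each list, with their number in brackets, and thick bars are list medians, with genes not well above background in 1 RNA at their measured values. Orange bars mark lists camera called higher, blue bars lists called lower and grey bars lists not called; medians run from 1.59 for epithelial junction genes to -6.29 for fibroblast genes, and with an estimated correlation no list was called.

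Among immune and stress genes, more were called lower than higher in iPS M13. Of 15 inflammatory cytokine and chemokine genes 14 were lower, with Ccl2 at -10.88 ± 0.07 (iPS M13 measured on 1 of 3 arrays), Cxcl1 at -8.87 ± 0.04, Ccl7 at -8.86 ± 0.04 and Cxcl2 at least 429-fold lower, and 1 was higher, Il18 (1.36 ± 0.00487), which averaged over its probes no longer reached 2-fold (0.93). The list median was -5.80 (adjusted p = 0.000556, and adjusted p = 0.336 with an estimated correlation). MHC class I and antigen processing genes had 13 of 15 lower and 0 higher. The class I gene RT1-S3 was at -4.35 ± 0.02 (-2.81 from another probe) and the immunoproteasome subunit Psmb8 was at least 31.1-fold lower. The list median was -2.52 (adjusted p = 0.000974, and adjusted p = 0.336 with an estimated correlation). Interferon response genes had 11 of 17 lower, with Ifitm3 at -7.49 ± 0.09, and 1 higher, Oasl (1.79 ± 0.16, mix1 measured on 2 of 3 arrays). Their median was -1.45, at an adjusted p = 0.00230 (adjusted p = 0.309 with an estimated correlation). Senescence and p53 target genes had 11 of 19 lower and 0 higher, with the stress genes Gadd45b (-4.59 ± 0.02), Gadd45a (-4.40 ± 0.03) and Gadd45g (-3.97 ± 0.01). Their median was -2.02, at an adjusted p = 0.00733 (adjusted p = 0.363 with an estimated correlation).

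Signalling genes were mostly lower too. LIF, STAT3 and feedback genes had 12 of 17 lower and 0 higher, with Klf4, Junb (-5.36 ± 0.05), the ERK phosphatase Dusp6 (-4.14 ± 0.03) and the receptor Fgfr1 (-5.48 ± 0.14, iPS M13 measured on 2 of 3 arrays). Their median was -2.24 (adjusted p = 0.00109, and adjusted p = 0.363 with an estimated correlation). WNT and BMP pathway genes had 16 of 21 lower, with the BMP antagonist Grem1 at -10.74 ± 0.07 (iPS M13 measured on 2 of 3 arrays; -7.04 from another probe, used when both channels had to be above background), Dkk3 at -6.90 ± 0.14 and Wnt5a at least 106-fold lower, and 1 higher, the WNT effector Lef1 (2.84 ± 0.18, mix1 measured on 1 of 3 arrays). Their median was -2.43 (adjusted p = 0.000410, and adjusted p = 0.309 with an estimated correlation).

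Among lysosome, cholesterol synthesis and ribosomal protein genes, more were called lower than higher. Lysosome genes had 19 of 21 lower, with the tetraspanin Cd63 at -7.58 ± 0.10 and the cathepsins Ctsb (-5.36 ± 0.16) and Ctsh (-5.32 ± 0.01), and 1 higher, Ctsz (1.12 ± 0.03). Their median was -2.93 (adjusted p = 2.25e-05, and adjusted p = 0.309 with an estimated correlation). Cholesterol synthesis genes had 15 of 21 lower and 0 higher, led by lanosterol synthase Lss (-3.76 ± 0.00469) and Sqle (-2.42 ± 0.02). Their median was -1.38 (adjusted p = 0.000556, and adjusted p = 0.336 with an estimated correlation). Ribosomal protein genes had 6 of 31 lower and 0 higher, with Rps16 at -2.12 ± 0.06, Rplp1 at -1.83 ± 0.06 and a median of -0.54 (adjusted p = 0.0133, and adjusted p = 0.363 with an estimated correlation). This call ended under median centring (-0.24), no within-array normalization (-0.30), the processed signals and value table (-0.14) and GC correction (-0.12). Glycolysis genes had 3 of 21 higher, with lactate dehydrogenase Ldhb at 2.32 ± 0.01, and 4 lower, with Eno2 at -5.06 ± 0.03 and the lactate exporter Slc16a3 at -4.85 ± 0.01 (adjusted p = 0.213 for the list). Oxidative phosphorylation genes had 3 of 26 higher, with cytochrome c, Cycs, at 1.66 ± 0.04, and 2 lower, Ndufa1 (-1.04 ± 0.01) and Cox4i1 (-1.04 ± 0.02), neither of which reached 2-fold under median centring or GC correction. The list was not called (adjusted p = 0.0784). Housekeeping reference genes had 1 of 14 higher, Tfrc, and 3 lower, including Actb (-3.77 ± 0.09) and Gusb (-1.91 ± 0.04). The median of that list, -0.17, turned to 0.55 at its highest under the other settings, and the list was not called (adjusted p = 0.553).

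The largest differences measured in both RNAs named further genes. On the higher side these included Arxes1 (6.83 ± 0.19), Bex1 (5.40 ± 0.01), the neuronal RNA-binding protein gene Elavl2 (5.20 ± 0.18), Alx1 (5.16 ± 0.14), Avil (4.80 ± 0.03), Resp18 (4.72 ± 0.01), the natriuretic peptide gene Nppb (4.66 ± 0.05), Smpd3 (4.62 ± 0.15) and Nfe2l3 (4.41 ± 0.08). On the lower side, Col3a1, with its probe on chromosome 9 from 44318879 to 44318938, Dcn, Myl9, Timp2, S100a4, Cxcl1 and Ccl7 were joined by Ccdc80 (-9.78 ± 0.14), the matrix Gla protein gene Mgp (-9.75 ± 0.11) and Col1a2 (-8.82 ± 0.17). For 720 of the genes called higher mix1 was not well above background on any array. Large bounds among them belonged to Sycp3l2, at least 61.8-fold higher, the secretory granule protein gene Chgb (at least 22.6-fold) and the cadherin Cdh17 (at least 22.3-fold). For 1158 of the genes called lower iPS M13 was not well above background, with the largest bounds for the interleukin receptor Il1rl1 (at least 917-fold lower), Gsta1 (at least 468-fold), Cxcl2, the endothelin receptor Ednrb (at least 386-fold) and Esm1 (at least 338-fold). These bounds rest on levels per channel, hold for the main settings only and are open to dye bias. Across the settings the log2 ratio of Il1rl1 ran from -12.23 to -7.04. At their smallest, Gsta1 was at -8.48, Ednrb at -8.32 and Esm1 at -8.38. Of 3116 genes with several measured probes, 7 had probes called in opposite directions. Probes of a gene could also differ in size, and these ranks rest on the probe used: another probe put Myl9 at -6.01.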

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

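The tests of X dose, of probe GC content on X-linked and neuroectoderm genes, and of neuron genes were chosen or completed after related results had been seen.

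The control probe AT_W_M, which took no part in the comparison, was well above background in iPS M13 on all 10 spots of all 3 arrays and in mix1 on 6.67% of them. Its median log2 ratio of processed signals was 2.94, which is no measured fold, since most mix1 spots were not well above background. The files do not say what it detects, and no explanation was tested.

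Log2 ratios fell with the GC content of the probe. Median ratios in 5 bins of genes from low to high GC were 0.38, 0.20, -0.06, -0.34 and -0.55, and the slope across genes was -0.43 per 10% GC. Among probes of the same gene it was -0.17 (95% bootstrap interval -0.22 to -0.13), which argues against probe GC content acting on the ratio as the whole cause. The within-gene slope was 40.6% of the slope across all genes (30.6 to 51.1), leaving 59.4% (48.9 to 69.4), and 23.7% (17.0 to 31.4) of the steeper slope of -0.73 across the same 3116 genes. Since a share over 50% was excluded by the second comparison and not by the first, a probe effect and a difference between genes of different GC content cannot be told apart as the larger part, and both may contribute.

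Of 710 X-linked genes 29.2% were higher in iPS M13, against 18.1% of 18556 autosomal genes (Fisher's exact test, two-sided, p = 1.71e-12; genes are not independent replicates), and single autosomes ran from 14.3% to 24.3%. The X minus autosome median log2 ratio was 0.18, and after GC correction 0.20 (0.06 to 0.30, permutation p = 0.000250). That argues against GC content as the cause of the shift in the median. The share called higher was not recomputed after GC correction. Over all genes that share fell from 28.4% in the lowest GC bin to 6.78% in the highest, so GC content stays open for the share. The permutation shuffled genes, so it leaves out the spread between chromosomes. Medians of single autosomes ran from -0.28 (chromosome 20) to 0.19 (chromosome 14), against 0.14 for X. After GC correction they ran from -0.21 (chromosome 20) to 0.13 (chromosome 4), against 0.18 for X. Of the 349 X-linked genes with a symbol, 98 shared the part of the name before the first digit with another and were taken as gene families. Leaving these 98 out left the X minus autosome median at 119% of its former size (0.26, permutation p = 0.0231). That argues against a few such families as the source of the median shift among genes with a symbol. X-linked genes without a symbol were not covered, so families among them stay untested. The share called higher was not recomputed without the 98 genes. The upper end of the GC-corrected X minus autosome interval, 0.299, lay under 1, so these ratios also argue against a 2-fold difference in X transcript dose. A smaller dose difference, and differences between the cell types of the RNAs, stay open as untested, and the labels give no donor sex.

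Of 9 neuroectoderm genes 6 were higher and 0 lower, and of the 6 only Nes had mix1 well above background on all 3 arrays. Neurons among the iPS M13 cells are a candidate source of the higher values. Of 15 measured genes on a list of 23 neuron genes, 73.3% were higher, including Stmn2 (2.58, log2 signal 15.51), Uchl1 (2.02, 15.07), Nefm (3.14) and Gap43 (2.40), while Ncam1 (-2.84) and Nefh (at least 3.45-fold) were lower. The list left out Thy1, whose lower value was known, and with it the share was 68.8%. Over all 23 genes it was 47.8%, since 8, including Syt1, Rbfox3, Syn1 and Syp, were not well above background, and 3 measured genes were also in the fixed lists with values already known. The neuroectoderm median kept 120% of its size after GC correction (1.36), which argues against GC content as its source. Camera with the preset correlation still called the list, at a larger adjusted p than before correction (adjusted p = 0.0200). Camera with an estimated correlation, before correction, did not call it (adjusted p = 0.336). Expression by the iPS cells themselves stays open.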

How the results depend on the processing

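The correction for probe GC content was chosen after the data were examined. Genes called higher numbered 7400 under median centring, 7005 without within-array normalization, and 6319 with the processed signals and 6319 with the value table made from them, against 3808. The cause was not tested. Without a minimum fold 19544 of 20343 genes passed the adjusted p, 9587 higher and 9957 lower, so the minimum fold decided nearly all calls. Camera with an estimated correlation called 0 lists, against 25 with the preset one, 23 on ranks and 34 by fry, which compares a list with no other genes. Estimated from 3 arrays, that correlation leaves few degrees of freedom, so the lack of calls decides little. Other counts of calls stayed within 1.5 times, and no called gene changed direction. Of the 3808 and 5184 calls, 2900 and 4560 were shared after GC correction. Leaving out 1 replicate gave 3733 to 3904 genes higher, 5144 to 5224 lower and 25 lists in each case. Outside these, 24 of 2531 values of named genes and 17 of 472 of lists changed their side of the threshold, and the cause was not tested; Aquantile scaling and the variance model leave ratios unchanged by construction. No paired analysis was possible because all samples formed 1 group. Slide and scan date were not run as a block, since all 3 arrays shared both. Signal over background limits 720 of the higher and 1158 of the lower calls to bounds and left 16835 probes untested.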

Other observations

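All genes in this part were chosen after their values were seen, and no explanation was tested for them.

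Genes of dense-core secretory granules, which store peptide hormones, went both ways in iPS M13. Of 12 such genes 10 were measured, with 6 higher and 3 lower. The granule genes Scg3 (3.76 ± 0.19, mix1 measured on 1 of 3 arrays) and Resp18 and the release factors Cadps (3.73 ± 0.23) and Cadps2 (3.85 ± 0.29), each with mix1 measured on 1 of 3 arrays, were higher, as were Chga and Chgb. The processing enzyme gene Cpe (-4.36 ± 0.01) and Vgf (-2.01 ± 0.05) were lower, and Scg2 was at least 8.59-fold lower. Scg5 (0.87 ± 0.02) was not called.

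The X-linked homeobox genes Rhox5 (3.83 ± 0.05) and Rhox9 (4.08 ± 0.19), known from reproductive tissue, were higher, and they were the only ones measured of 13 listed. The neuronal RNA-binding protein genes Elavl4 (4.29 ± 0.13) and Elavl3 (1.62 ± 0.03) were higher along with Elavl2.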
